A study of Mus musculus with 16 samples.

How the data were processed

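MeCP2 chromatin immunoprecipitation followed by sequencing was carried out on forebrain, meaning cortex and hippocampus, of male C57BL/6 mice, per the labels. The sample characteristics give an age of 8 weeks, while the protocol text gives a wider range. Wild-type (WT) and Mecp2 knockout (KO) tissue was used. Each genotype had libraries from 2 MeCP2 antibodies, from a serum without MeCP2 antibody and from input chromatin. Antibody 1 (Ab1) is the serum of Chen et al. and antibody 2 (Ab2) is a commercial antibody from Sigma. The serum control is pre-immune serum for Ab1 per the labels' protocols, and the sample titles call it IgG. With 2 libraries in each of the 8 groups, 16 libraries were used. Other chromatin marks and genotypes named in the series design were not analysed here.

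The authors deposited 1 table with a whole-number count of reads per gene for each library, and these counts were used as deposited. Per the file headers, each gene was counted from 3 kb downstream of its transcription start to its end, so promoters are left out. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2 2.2.9, SAMtools 0.1.19 and bedtools were used with mouse build mm10. The counting rule, the treatment of duplicate reads and any equalising of depth are not given in the sources used here. The table also gives per gene 4 columns headed mCA, CA, mCG and CG, which belong to none of the listed samples. As mCA never exceeded CA and mCG never exceeded CG, they were taken as methylated calls and all calls at CA and CG positions. Their methylome is not named in the sources used here. The table has 17929 genes with counted spans from 1501 bp to 2268 kb (median 20.3 kb). Gene symbols are those of the table, and 17282 of them (96.4%) matched the RefSeq gene list, 601 by a synonym. Spans of 641 genes overlapped other listed genes over more than 50 percent of their length, and reads there cannot be assigned to 1 gene.

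Totals over all genes ran from 5593558 to 6506231 reads per library, with medians of 106 to 121 reads per gene. Libraries of 1 group differed by more than counting noise in all 8 groups (chi-square per degree of freedom 1.13 to 1.21 over genes with at least 20 reads, highest p = 3.6e-32), so each was kept as its own library. The labels do not say that replicates were separate animals. The p-values therefore measure the spread between these libraries, which may be technical. With 2 libraries against 2, an exact permutation test on a single value cannot go below p = 0.333, so all tests came from models fitted across genes. Genes under 10 kb had a median of 25.8 reads, so counting error is largest in short genes.

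Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passing edgeR's expression filter by group were kept (17834 tested, 95 removed). Library sizes were scaled by TMM, 1 model with a mean for each of the 8 groups was fitted to all 16 libraries, and quasi-likelihood F tests were two-sided. Benjamini-Hochberg adjustment was made over all genes tested, with a threshold of 0.05. The common dispersion was 0.00048. TMM centres the bulk of genes, so each log2 fold change is relative to the average gene and says nothing of a change shared by all genes. Levels are TMM-scaled CPM. The planned comparisons, 12 in number, were WT against KO in each kind of library, precipitates against input within a genotype, the genotype effect corrected for input, and the difference between antibodies. Another 5 comparisons against pre-immune serum or of pre-immune serum against input in KO were added after the data were seen.

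Gene groups were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the groups of 1 kind within a comparison. The groups were 6 classes of counted span and 11 gene lists. The lists hold 344 genes, of which 38 were not in the table. Camera sets the genes of a group against all others, and genes are not independent replicates. It compares test statistics per gene, which grow with read count, so its p-values do not test the medians given beside them. The long-gene difference is the median log2 fold change of genes with spans over 100 kb minus that of the rest. Analyses by methylation were chosen after the data were seen. They used 16467 genes with at least 500 CA and 500 CG calls. These were divided into 10 classes of equal size by the percentage of CA calls that were methylated (mCA level). The mCA difference is the median log2 fold change of the highest class minus that of the lowest. That difference was not itself tested, and it is said to pass where camera called the highest class against all other genes.

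Genes to name were set by rule. In each of the 4 main comparisons (both antibodies, WT against KO and over input in WT) these were Mecp2, the 4 largest rises and 4 largest falls, and from each list the 2 measured members with the smallest p. The rises and falls were taken among genes with an adjusted p under 0.05, a mean count of at least 50 and no overlap between the groups' libraries. In the other comparisons they were Mecp2 and the 5 genes with the smallest p. Some genes are also given, outside the rule, in comparisons for which it did not select them.

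Alternatives were DESeq2 1.42.0 with its own scaling and its own filter, which leaves genes with low counts without an adjusted p, DESeq2 size factors in edgeR, library totals, unscaled counts, no filter, a mean count of at least 50, the compared groups alone, replicate blocks, each library left out, other length boundaries, non-overlapping genes, other methylation call minimums, and a fit without chromosome Y and unplaced contigs. A correction for GC content was left out because no genome sequence was used here. The scripts were tested on simulated counts of all 16 libraries over 17805 genes, drawn from group means, with the KO Ab1 means used also for WT Ab1. Changes were then put into WT Ab1 at genes with a mean count of at least 20. Of the changed genes, 26.9% were recovered at 1.2-fold (67 genes), 65.7% at 1.5-fold (67 genes) and 95.5% at 2-fold (66 genes). Of 17605 unchanged genes, 8 were called. Far fewer genes were changed here than were called in the data for Ab1 in WT against KO (2382). Benjamini-Hochberg adjustment is stricter where few genes change, so these shares may not hold for the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.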

Results

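MeCP2 binds methylated DNA and is abundant in neurons, and its loss causes Rett syndrome in humans. Its occupancy over gene bodies was measured in mouse forebrain as reads per gene in 16 libraries. WT and KO tissue each had 2 libraries with antibody 1 (Ab1), 2 with antibody 2 (Ab2), 2 with pre-immune serum for Ab1, and 2 of input. The series concerns the repression of transcriptional initiation by MeCP2 at long, highly methylated genes, so the comparisons ask at which genes the antibody signal depended on MeCP2. Total counts were 5948269 to 6099777 reads in the 4 WT antibody libraries. They were 5593558 to 5741901 in the 8 KO antibody and pre-immune libraries, counting both genotypes for pre-immune serum, and 6355929 to 6506231 in the 4 inputs. All 17834 genes tested had counts summed from 3 kb past the start to the end of the gene, in mm10 coordinates.

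Mecp2 itself, the gene removed in KO, is on chromosome X at 74026592 to 74082690. Its counted span held 40.4 ± 3.84 CPM in WT input and 37.3 ± 0.415 CPM in KO input (SD, n = 2 each). With Ab1 it held 30.5 ± 2.19 CPM in WT and 34.4 ± 3.53 CPM in KO, and with Ab2 29.3 ± 1.31 CPM in WT and 33.2 ± 2.07 CPM in KO. Pre-immune serum gave 34.9 ± 0.934 CPM in WT and 33.0 ± 0.321 CPM in KO. No difference between WT and KO passed the test in any kind of library (adjusted p = 0.33 with Ab1 and 0.35 with Ab2, higher with pre-immune serum and input). Counts over this whole span, of which the labels do not say what was deleted, therefore do not check the genotype labels.

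With Ab1, 11 of 25 excitatory neuron markers and 16 of 45 long neuronal genes were higher in WT than in KO, against 1318 of all 17834 genes. Of 40 ubiquitously expressed genes 2 were lower, which is no excess over the 1064 lower among all genes. With an estimated correlation the excitatory list passed (adjusted p = 0.0032), but not the long neuronal (adjusted p = 0.19) or the ubiquitous list (adjusted p = 0.14). Auts2, a regulator of transcription linked to autism (chromosome 5, 131437682 to 132539343) had 1405 ± 25.9 CPM in WT and 1133 ± 10.1 CPM in KO (SD, n = 2 each), a log2 fold change of 0.31 (SE 0.03, adjusted p = 5.5e-13). The teneurin Tenm3 (chromosome 8, 48225665 to 48671690), which guides neuronal wiring, was higher by 0.34 (SE 0.04, adjusted p = 5.4e-12). At the other end, the oocyte gene Nlrp5 (chromosome 7, 23388889 to 23441923) had 16.8 ± 0.466 CPM in WT and 32.6 ± 1.70 CPM in KO, a log2 fold change of −0.96 (adjusted p = 1.5e-08). Of all genes, 2382 differed, 1318 higher and 1064 lower in WT, with a median absolute log2 fold change of 0.32.

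Among the largest Ab1 rises, A930004D18Rik (chromosome 2, 18025187 to 18034741) had 17.7 ± 2.26 CPM in WT and 8.03 ± 2.04 CPM in KO (log2 fold change 1.14, SE 0.18, adjusted p = 7.3e-07). Dhrsx, listed on an unplaced contig, differed by 1.14 (adjusted p = 3.1e-12). Vps37b, of the ESCRT-I sorting complex, differed by 0.88 and the claudin Cldn12 by 0.86. With Ab2 the same pair of genes, outside the rule there, had values of 0.41 (adjusted p = 0.087) and 0.49 (adjusted p = 0.14), which did not pass. E330014E10Rik (−1.03), Gm6367 (−0.97) and the vomeronasal receptor gene Vmn2r116 (−0.95) completed the largest falls, and where near-identical copies of such genes exist their reads cannot be told apart. Cldn12 did not pass without replicate 1 of WT Ab1 (0.73) or of KO Ab1 (0.55), and Vps37b did not pass without replicate 2 of KO Ab1 (0.56). DESeq2's own filter on low counts left A930004D18Rik (1.14), Cldn12 (0.86) and Vmn2r116 (−0.95) without an adjusted p, and Gm6367 did not pass its test (−0.97, adjusted p = 0.092).

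Among the fixed lists, excitatory neuron markers had the clearest Ab1 difference. Of 25 members, 11 were higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 0.17 (adjusted p = 1.7e-09, and adjusted p = 0.0032 with an estimated correlation). They included the upper-layer factor Cux1 (0.32, adjusted p = 1.0e-08) and the deep-layer factor Bcl11b (0.53, adjusted p = 7.0e-07). Of 45 long neuronal adhesion and synapse genes, 16 were higher and 0 lower (17 and 0 adjusted over the list alone), with a median of 0.042 (adjusted p = 1.7e-07, but adjusted p = 0.19 with an estimated correlation). Of these 45 members, 44 have spans over 100 kb. All 2225 genes over 100 kb had a median of 0.067, with 676 higher and 187 lower, so the list median lay below that of long genes in general. Genes named as MeCP2 targets in earlier work had 8 of 28 members higher and 0 lower (10 and 2 adjusted over the list alone), among them the ephrin receptor Epha7 (0.31, adjusted p = 1.4e-06), with adjusted p = 0.00043 and adjusted p = 0.073 with an estimated correlation.

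Astrocyte, oligodendrocyte and activity-regulated lists passed with Ab1 with the preset correlation, but not with an estimated correlation (adjusted p = 0.073, 0.083 and 0.073). Astrocyte markers had 4 of 21 members higher and 0 lower (4 and 0 adjusted over the list alone; median 0.15, adjusted p = 0.021), including the Hedgehog factor Gli3 (0.18) and the bicarbonate transporter Slc4a4 (0.16). Oligodendrocyte lineage markers had 3 of 24 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.04), with the myelin gene Mbp at 0.48 (adjusted p = 1.4e-07) and the Wnt effector Tcf7l2 at 0.29 (adjusted p = 2.0e-05). Activity-regulated genes had 4 of 21 higher and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.019). They included the sorting receptor Sorcs3 (0.15) and the immediate-early factor Egr3 (2.07, adjusted p = 5.3e-05), whose WT and KO levels of 4.90 and 1.15 CPM rest on few reads. Ubiquitously expressed genes had a median of −0.14 with 2 of 40 members lower, the splicing factors Prpf8 (−0.64, adjusted p = 0.0037) and Sf3b1 (−0.26, adjusted p = 0.048), and 1 lower adjusted over the list alone. That list had adjusted p = 0.0032, but adjusted p = 0.14 with an estimated correlation. Its members had a median mCA level of 1.02%, and those of the excitatory list 3.88%. List differences were not tested apart from mCA or length.

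No Ab1 difference between WT and KO was found for the remaining lists as groups. Inhibitory neuron markers had 2 of 21 higher (2 adjusted over the list alone; adjusted p = 0.48), the interneuron factor Sox6 (0.23, adjusted p = 5.6e-08) and the secreted glycoprotein Reln (0.11, adjusted p = 0.021). Microglia and vascular markers had 2 of 26 lower (1 adjusted over the list alone; median −0.027, mean 0.013, adjusted p = 0.86), the barrier transporters Slco1a4 (−0.30) and Abcb1a (−0.19). Genes of liver, muscle, blood and skin had 1 of 38 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.57): the urea cycle gene Cps1 (0.17) and the liver P450 gene Cyp3a11 (−0.58). MeCP2 partners and DNA methylation enzymes had 1 of 23 higher, Mbd2 (0.25), and 1 lower, Cdkl5 (−0.19), with 1 and 0 adjusted over the list alone (adjusted p = 0.98).

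Several of these smaller calls ended when 1 library was left out, and none of the genes named here changed sign. A call can then end although the value did not shrink, as 1 library is left in that group. Without replicate 1 of WT Ab1 the calls ended for Prpf8 (−0.40), Cyp3a11 (−0.45), Reln (0.12), Slco1a4 (−0.29) and Cps1 (0.16). Without replicate 2 of WT Ab1 they ended for Sf3b1 (−0.17), Reln (0.11), Gli3 (0.15), Slco1a4 (−0.30) and Abcb1a (−0.13). The same held there for Cps1 (0.19), Mbd2 (0.18), Cdkl5 (−0.11) and Sorcs3 (0.13). Without replicate 1 of KO Ab1 they ended for Sf3b1 (−0.13), Reln (0.13), Gli3 (0.15), Slco1a4 (−0.26) and Abcb1a (−0.16). Cps1 (0.13), Mbd2 (0.27) and Cdkl5 (−0.071) also did not pass there. Without replicate 2 of KO Ab1 they ended for Prpf8 (−0.51), Cyp3a11 (−0.52), Reln (0.10) and Slc4a4 (0.13). Abcb1a (−0.22), Mbd2 (0.23) and Sorcs3 (0.13) did not pass there either. The call of Sf3b1 also ended without any of the 4 inputs (−0.26). DESeq2 gave no adjusted p to Egr3 and Cyp3a11, and did not call Prpf8, Sf3b1, Reln, Slco1a4, Abcb1a, Cps1, Mbd2 or Cdkl5.

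For Ab1 WT against KO, DESeq2 called 949 of the 9934 genes to which its filter left an adjusted p, and edgeR 2382 of 17834. Leaving out replicate 2 of KO Ab1 left 1265 calls (746 higher, 519 lower) and leaving out replicate 2 of WT Ab1 left 1268 (713 higher, 555 lower), and without replicate 1 of WT Ab1 681 were lower. Of the calls, 55.3% were higher in WT with TMM, 41.3% with library totals and 77.6% with unscaled counts, so the balance of higher and lower depends on the scaling. Without replicate 1 of KO Ab1 or replicate 2 of WT Ab1, the astrocyte and oligodendrocyte lists no longer passed with the preset correlation, nor did the oligodendrocyte list with the replicate number as a block.

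With Ab2, Auts2 and Tenm3 were again higher in WT than in KO. Auts2 had 1403 ± 33.9 CPM in WT and 1136 ± 18.4 CPM in KO (SD, n = 2 each), a log2 fold change of 0.30 (SE 0.03, adjusted p = 4.3e-13), and Tenm3 was higher by 0.24 (adjusted p = 5.1e-07). The largest rises were Dhrsx (1.37), A930004D18Rik (0.95, adjusted p = 2.8e-05), the pituitary factor gene Pou1f1 (0.71, chromosome 16, 65523629 to 65533981) and 5430403N17Rik (0.70). The largest falls were Gm10487 (−1.17), 4933407K13Rik (−1.10), the Mas-related receptor gene Mrgpra1 (−1.01) and the multicopy chromosome Y gene Sly (−0.99). In all, 1732 genes differed, 1034 higher and 698 lower, with a median absolute log2 fold change of 0.31. DESeq2's filter left these 8 genes without an adjusted p, with log2 fold changes that included 1.37 for Dhrsx and −1.18 for Gm10487.

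Excitatory neuron markers again had a difference with Ab2. Of 25 members, 7 were higher and 0 lower (9 and 0 adjusted over the list alone; median 0.082), with adjusted p = 1.5e-05 and adjusted p = 0.02 with an estimated correlation. Cux1 was higher by 0.39 (adjusted p = 3.6e-11) and its paralog Cux2 by 0.35 (adjusted p = 1.3e-05). Astrocyte markers had 3 of 21 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.18), with adjusted p = 0.0031 and adjusted p = 0.046 with an estimated correlation, including Gli3 (0.22) and Gli2 (0.23). Long neuronal adhesion and synapse genes had 10 of 45 higher and 2 lower (14 and 2 adjusted over the list alone; median 0.03), with adjusted p = 0.001 and adjusted p = 0.38 with an estimated correlation. All 2225 genes over 100 kb had a median of 0.052 with Ab2. The targets named in earlier work had 6 of 28 higher and 0 lower (9 and 0 adjusted over the list alone), with adjusted p = 0.0017 and adjusted p = 0.11 with an estimated correlation, Epha7 at 0.36 among them. Oligodendrocyte lineage markers had 3 of 24 higher and 0 lower, the same adjusted over the list alone, with Mbp at 0.37 and Tcf7l2 at 0.29 (adjusted p = 0.044, and adjusted p = 0.11 with an estimated correlation). That list did not pass with the replicate number as a block.

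The other lists did not differ as groups with Ab2. Ubiquitously expressed genes had a median of −0.089 with 0 of 40 members passing edgeR's test (0 adjusted over the list alone; adjusted p = 0.065); Prpf8 had −0.36 (adjusted p = 0.17) and the deubiquitinase Usp7 −0.19 (adjusted p = 0.21). Inhibitory neuron markers had 2 of 21 higher (2 adjusted over the list alone; adjusted p = 0.26), Sox6 (0.24, adjusted p = 5.2e-08) and Reln (0.11). Microglia and vascular markers had 1 of 26 lower, the angiopoietin receptor Tek (−0.17), and 0 adjusted over the list alone (median 0.033, mean −0.028, adjusted p = 0.95), and Abcb1a had −0.19 (adjusted p = 0.062). None of 38 genes of liver, muscle, blood and skin passed (median 0.0008, mean −0.031, adjusted p = 0.72), with Dsg3 at −0.31 and Cps1 at 0.14, nor did any of 23 MeCP2 partners and methylation enzymes (adjusted p = 0.37), with Tet1 at 0.20 and Dnmt1 at −0.26. Activity-regulated genes had 2 of 21 higher (2 adjusted over the list alone; adjusted p = 0.37), Sorcs3 (0.12) and Egr3 (1.06, adjusted p = 0.046). Several of these calls ended when 1 Ab2 library was left out, with no change of sign and not always with a smaller value. Without replicate 1 of WT Ab2 the calls ended for Tek (−0.11) and Egr3 (0.81). Without replicate 2 of WT Ab2 they ended for Reln (0.075), Gli2 (0.16) and Sorcs3 (0.081), while Abcb1a and Tet1 passed. Without replicate 1 of KO Ab2 they ended for Reln (0.086), Gli2 (0.19), Sorcs3 (0.10) and Egr3 (1.19). Without replicate 2 of KO Ab2 they ended for Gm10487 (−0.71), Mrgpra1 (−0.65), Reln (0.13), Tek (−0.12), Sorcs3 (0.13) and Egr3 (0.95). The call of Egr3 ended also without either WT input (1.06), and DESeq2 gave no adjusted p to Egr3 and did not call Tek, Sorcs3 or Reln.

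For Ab2 WT against KO, DESeq2 called 650 of the 6111 genes to which its filter left an adjusted p. Without 1 of the Ab2 libraries the edgeR count ran from 731 (replicate 2 of KO, 495 higher and 236 lower) over 863 (replicate 1 of WT, 570 and 293) and 1032 (replicate 2 of WT, 599 and 433) to 1055 (replicate 1 of KO, 594 and 461). The share of calls that were higher in WT was 59.7% with TMM, 44.2% with library totals and 79.3% with unscaled counts. The call of the long neuronal list ended without replicate 1 of WT Ab2 or replicate 2 of KO Ab2 and with library totals, and that of the oligodendrocyte list without replicate 1 or 2 of KO Ab2 or replicate 2 of WT Ab2. Ubiquitously expressed genes passed as a list without replicate 1 of WT Ab2 or replicate 2 of KO Ab2.

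Many genes differed with both antibodies. With no library in common, there were 687 genes higher in WT with both antibodies, against 76.4 for independent lists, and 411 genes lower in WT with both antibodies, against 41.6. No gene was called in opposite directions, and 96.6% of the Ab1 calls had the same sign with Ab2. Without replicate 2 of KO Ab2 these overlaps were 383 and 155, without replicate 1 of WT Ab2 434 and 175, and without replicate 2 of WT Ab1 449 were higher with both. Without replicate 2 of KO Ab1 242 were lower with both. Whether both antibodies were used on the same chromatin is not stated, and shared chromatin would add to this overlap. No gene passed edgeR's test for a difference in genotype effect between the antibodies (728 at an unadjusted p under 0.05, and DESeq2 called 0 with 105 unadjusted). Mecp2 had 0.01 in this comparison (SE 0.16), and the genes with the smallest p were Tmem154 (0.63), Txndc9 (−0.98), Lect2 (−1.85), Cnot9 (−0.69) and Cdc42bpb (0.42), none of which passed. Of the 11 lists, long neuronal genes (median 0.025) and excitatory neuron markers (median 0.053) differed between the antibodies, each with adjusted p = 0.03, but with adjusted p = 0.80 and 0.21 with an estimated correlation. Genes over 100 kb exceeded the others by 0.014 (p = 0.15 by camera with the preset correlation), which passed without replicate 1 of WT Ab2 (0.016), replicate 1 of KO Ab1 (0.025) or replicate 2 of KO Ab2 (0.026).

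Grouped by length, long genes had more antibody reads in WT than in KO. The median log2 fold change with Ab1 was −0.03 for spans under 10 kb, −0.045 for 10 to 25 kb, −0.024 for 25 to 50 kb, 0.028 for 50 to 100 kb, 0.059 for 100 to 200 kb (adjusted p = 8.7e-07) and 0.076 for spans over 200 kb (adjusted p = 1.9e-15). With Ab2 the class of 100 to 200 kb had 0.054 (adjusted p = 7.4e-07) and that over 200 kb 0.051 (adjusted p = 5.8e-12). The 2225 genes over 100 kb lay above the 15609 others by 0.089 with Ab1 (p = 1.1e-12, and p = 0.0004 with an estimated correlation) and by 0.067 with Ab2 (p = 3.2e-11, and p = 0.00064 with an estimated correlation). Of these long genes, 676 were higher and 187 lower with Ab1, and 553 and 144 with Ab2. With the preset correlation the same difference did not pass camera with pre-immune serum (0.0032, p = 0.72) or in input (−0.0076, p = 0.25). Genes under 10 kb had a median of 25.8 reads and those over 200 kb 2103. The p-values and counts of calls by length therefore also reflect read depth.

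Grouped by gene-body mCA, an analysis chosen after the data were seen, the differences were wider than those by length. In the class of lowest mCA (0.427 to 1.11% of CA calls methylated, 1647 genes) the median log2 fold change was −0.22 with Ab1, with 1 gene higher and 300 lower (adjusted p = 2.4e-15, and adjusted p = 0.00015 with an estimated correlation). In the class of highest mCA (4.84 to 11.9%) it was 0.18, with 447 genes higher and 1 lower (adjusted p = 2.6e-24, and adjusted p = 0.005 with an estimated correlation). With Ab2 these classes had −0.19, with 0 genes higher and 210 lower, and 0.19, with 424 higher and 0 lower. Nlrp5, at 0.687% mCA, and A930004D18Rik, at 10.0% mCA, lie in the lowest and highest classes. The highest minus the lowest class was 0.41 with Ab1, 0.38 with Ab2, −0.021 with pre-immune serum and −0.023 in input. Replicate numbers shared a small difference in reads along mCA, given with the replicate block. Between libraries of the same number, a split chosen after the data were seen, the highest minus the lowest class was 0.36 and 0.45 with Ab1 (replicates 1 and 2), 0.37 and 0.38 with Ab2, and 0.0071 and −0.050 with pre-immune serum. The long-gene difference between such libraries was 0.071 and 0.10 with Ab1, and 0.074 and 0.065 with Ab2.

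Length and mCA are related, as median mCA was 2.31% in genes under 10 kb and 3.51% in genes over 200 kb. Across 16467 genes, which are not independent replicates, the rank correlation of the Ab1 difference was 0.41 with mCA, −0.23 with the CG methylation level and 0.076 with span. Given the others, the partial rank correlation was 0.41 for mCA, −0.23 for CG methylation and −0.024 for span. With Ab2 the correlation was 0.45 for mCA and −0.18 for CG methylation. The partial rank correlations were 0.45 for mCA, −0.18 for CG methylation and −0.047 for span. For CG methylation the sign depended on the comparison. Over input in WT its partial rank correlation was 0.30 with Ab1 and 0.31 with Ab2. Over input it was 0.41 with pre-immune serum in WT and 0.40 with either antibody in KO. Whether this background sets the negative sign in WT against KO was not tested. Within 5 classes of mCA, from lowest to highest, long genes exceeded others with Ab1 by 0.044, 0.045, 0.054, 0.022 and 0.0049, and with Ab2 by 0.0074, 0.039, 0.030, 0.0052 and −0.0037. Within length classes, genes of high mCA exceeded those of low mCA by 0.24 to 0.34 with Ab1 and by 0.27 to 0.38 with Ab2, and the low group of the longest class has 26 genes.

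**Figure D1:**
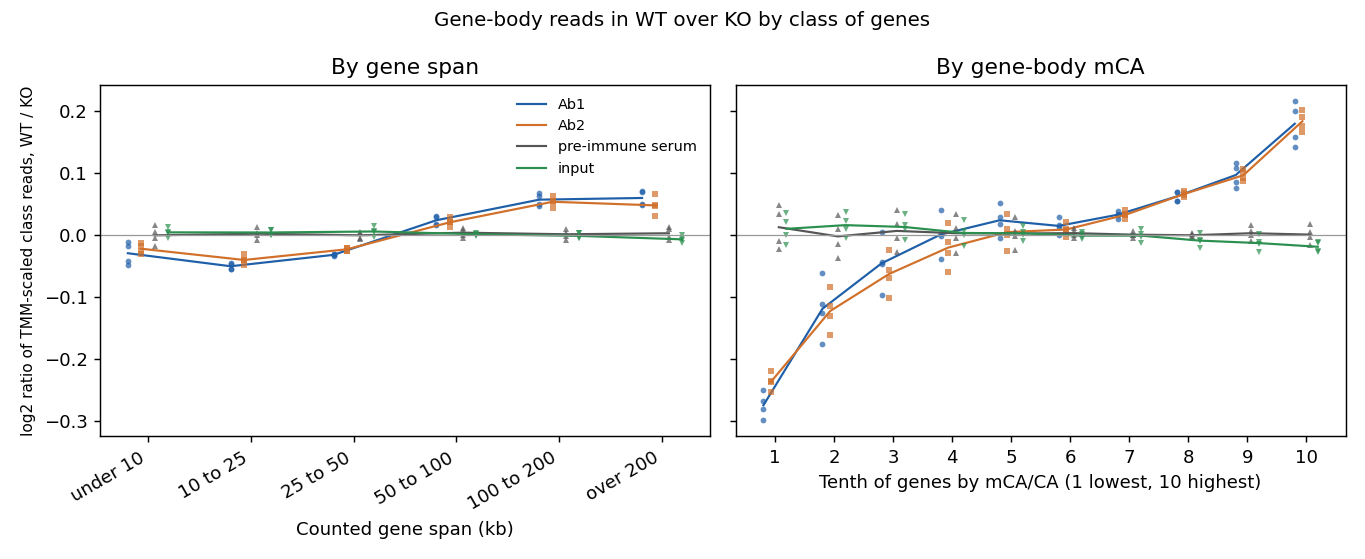
Log2 ratio of TMM-scaled reads in WT over KO, summed over genes of each counted span in kb (left) and over genes of each mCA class from 1, lowest, to 10, highest (right). Points are the 4 ratios between 2 WT and 2 KO libraries, lines their means; Ab1 and Ab2 run from below 0 to above 0 on both axes, while pre-immune serum and input stay near 0.

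Pre-immune serum, which holds no MeCP2 antibody, gave 1 gene that differed between WT and KO. This gene, 4933407K13Rik (chromosome X, 75725458 to 75761699), was lower in WT with a log2 fold change of −0.94 (SE 0.17, adjusted p = 0.0066), with 9.37 CPM in WT and 17.9 CPM in KO. It was lower in WT also with Ab2 (−1.10, adjusted p = 2.9e-06) and, outside the rule, with Ab1 (−0.69, adjusted p = 0.0027). In input it had −0.71 (SE 0.15, adjusted p = 0.093). The next genes with pre-immune serum were the kinase gene Prkd2 (−0.75, adjusted p = 0.12), St6galnac1 (−1.09), Ssh3 (−1.33) and 1700013F07Rik (−1.16), which did not pass, and Mecp2 had 0.08. All 11 lists had 0 members passing edgeR's test with pre-immune serum (0 adjusted over the list alone; adjusted p = 0.85 for each). Across genes, 744 had an unadjusted p under 0.05 and DESeq2 called 0 (89 unadjusted), and the call of 4933407K13Rik ended without replicate 1 of WT or of KO pre-immune serum. Prkd2 passed without either replicate of WT Ab2, which changes the shared estimate of spread.

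Input, which reads DNA content and chromatin yield, gave 0 genes by edgeR's test (694 at an unadjusted p under 0.05, and DESeq2 called 0 with 67 unadjusted). After 4933407K13Rik the smallest p-values belonged to the survivin gene Birc5 (1.29), Cckar (0.96), Ankrd45 (0.41) and Cib3 (1.17), and Mecp2 had 0.12 (SE 0.10). No list differed (lowest adjusted p = 0.32), with 0 members passing in all 11 lists, also adjusted over the list alone. Without replicate 1 of WT input, long neuronal genes (−0.024 relative to all genes) and the targets named in earlier work (−0.047) passed as lists, and with the input libraries alone in the fit 4933407K13Rik passed.

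Over input in WT, long neuronal genes passed as a list upward and ubiquitously expressed genes downward with both antibodies with the preset correlation. Neither list passed with an estimated correlation (adjusted p = 0.076 and 0.15 for the long neuronal list, 0.054 and 0.06 for the ubiquitous list, Ab1 and Ab2). The adhesion gene Sdk1 had 1052 ± 45.3 CPM with Ab1 against 798 ± 14.1 CPM in input (SD, n = 2 each), a log2 fold change of 0.40 (adjusted p = 9.5e-18), and 0.42 with Ab2. The growth factor gene Fgf5 (chromosome 5, 98257184 to 98277033) had the largest log2 fold change, with 0.97 for Ab1 (SE 0.12, adjusted p = 2.8e-10) and 0.89 for Ab2 (adjusted p = 6.6e-09). Mecp2 was lower than input, by −0.40 with Ab1 (adjusted p = 0.0014) and −0.46 with Ab2 (adjusted p = 0.00026). In all, 4854 genes differed with Ab1 (2658 higher, 2196 lower) and 5103 with Ab2 (2839 higher, 2264 lower), with a median absolute log2 fold change of 0.34 for each.

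The other largest values above input with Ab1 were Zadh2 (0.90), Dhrsx (0.86) and the vitamin D hydroxylase gene Cyp24a1 (0.85). Those with Ab2 were the enamel gene Ambn (0.86), Gm30332 (0.85), whose span lies wholly within other genes, and the vomeronasal gene Vmn2r52 (0.84). The largest values below input were led by Ttyh1, with −1.20 for Ab1 and −1.28 for Ab2, whose span is 58.9% overlapped by other genes. Next came the JNK scaffold gene Mapk8ip1 (−1.06), the adenylate kinase gene Ak1 (−1.03) and Pttg1ip (−1.02) with Ab1. With Ab2 these were Dusp8 (−1.22), the histone demethylase gene Kdm6b (−1.10) and Dpf1 (−1.07). DESeq2's filter left Zadh2, Cyp24a1, Ttyh1, Mapk8ip1 and Ak1 with Ab1, and Ambn, Ttyh1, Dusp8, Kdm6b and Dpf1 with Ab2, without an adjusted p. Mecp2 with Ab1 did not pass without replicate 2 of WT Ab1 or replicate 1 of WT input. With unscaled counts the median of all genes was −0.13 with Ab1 and −0.14 with Ab2, so above and below input mean relative to the average gene.

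Long neuronal adhesion and synapse genes had 26 of 45 members above input and 3 below with Ab1 (26 and 4 adjusted over the list alone; median 0.12, adjusted p = 1.5e-13) and 24 and 4 with Ab2 (25 and 4 adjusted over the list alone; adjusted p = 1.6e-08). With an estimated correlation they had adjusted p = 0.076 and 0.15. The glypican Gpc6 was a member (0.32 with Ab1, adjusted p = 8.6e-16, and 0.30 with Ab2). Ubiquitously expressed genes had 0 of 40 above and 16 below with Ab1 (0 and 19 adjusted over the list alone; median −0.26, adjusted p = 2.9e-07) and 18 below with Ab2 (20 adjusted over the list alone; adjusted p = 8.3e-06), with adjusted p = 0.054 and 0.06 with an estimated correlation. Among them, the ubiquitin ligase gene Ubr4 had −0.43 with Ab1 and −0.42 with Ab2, and the clathrin gene Cltc −0.44 and −0.38.

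Inhibitory neuron markers passed over input with the preset correlation and excitatory neuron markers did not, and a difference between these lists was not tested. Inhibitory neuron markers had 7 of 21 above and 1 below with each antibody (7 and 1 adjusted over the list alone with Ab1, 7 and 2 with Ab2; adjusted p = 0.00085 and 0.00098), with adjusted p = 0.054 and 0.06 with an estimated correlation. Sox6 had 0.53 with Ab1 (adjusted p = 1.7e-24) and 0.51 with Ab2, Erbb4 had 0.29 with Ab1 and Reln 0.37 with Ab2. Excitatory neuron markers had 8 of 25 above and 5 below with Ab1 (9 and 5 adjusted over the list alone; adjusted p = 0.25) and 8 and 6 with Ab2 (10 and 8 adjusted over the list alone; median 0.012, mean −0.065, adjusted p = 0.91). Foxp2 was above input with both (0.37 and 0.38), Zbtb20 above it with Ab1 (0.29) and Arpp21 below it with Ab2 (−0.56). Without a filter or with DESeq2, the median of the inhibitory list with Ab2 lay below that of all genes (−0.017 in each).

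Markers of oligodendrocytes, of microglia and vessels and of other tissues were above input with at least 1 antibody with the preset correlation, and none of these lists passed with an estimated correlation. Oligodendrocyte markers had 9 of 24 above and 0 below with Ab1 (9 and 0 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.076 with an estimated correlation) and 7 and 0 with Ab2 (7 and 0 adjusted over the list alone; adjusted p = 0.065), with St18 at 0.34 for each antibody and Tcf7l2 at 0.37 and 0.31. Microglia and vascular markers had 7 of 26 above and 0 below with Ab1 (8 and 1 adjusted over the list alone; adjusted p = 0.01) and 10 and 1 with Ab2 (10 and 1 adjusted over the list alone; adjusted p = 0.0048), including Ebf1 (0.40 and 0.39) and Dock8 (0.28 and 0.37). With an estimated correlation that list had adjusted p = 0.073 and 0.06. Genes of liver, muscle, blood and skin had 6 of 38 above and 0 below with Ab1 (5 and 0 adjusted over the list alone; adjusted p = 0.019) and 7 and 0 with Ab2 (7 and 0 adjusted over the list alone; adjusted p = 0.0073), with Cps1 at 0.52 and 0.47 and the titin gene Ttn at 0.41 and 0.44. It had adjusted p = 0.076 and 0.066 with an estimated correlation. Astrocyte markers had 6 of 21 above and 2 below with each antibody (7 and 2 adjusted over the list alone with Ab1, 6 and 2 with Ab2; adjusted p = 0.10 and 0.16), with Gli3 at 0.43 and 0.42 and Gli2 at 0.23 and 0.31, where Gli2 with Ab1 did not pass without replicate 2 of WT Ab1. Without replicate 1 of WT Ab1 the astrocyte list passed with Ab1 (0.21 relative to all genes), and without replicate 1 of WT Ab2 the oligodendrocyte list passed with Ab2 (0.16).

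MeCP2 partners and methylation enzymes had 1 of 23 above and 8 below with Ab1 (1 and 8 adjusted over the list alone; adjusted p = 0.00098) and 0 and 9 with Ab2 (0 and 10 adjusted over the list alone; adjusted p = 0.00016). They included the corepressor gene Ncor2 (−0.57 with each), Cdkl5 (−0.41 with Ab1) and Dnmt3a (−0.52 with Ab2), and with an estimated correlation the list had adjusted p = 0.11 and 0.094. The targets named in earlier work had 6 of 28 above and 6 below with Ab1 (7 and 7 adjusted over the list alone; median −0.053, test upward, adjusted p = 0.84) and 6 and 5 with Ab2 (6 and 6 adjusted over the list alone; adjusted p = 0.90), with Reln at 0.36 for Ab1. Activity-regulated genes had 2 of 21 above and 3 below with Ab1 (2 and 3 adjusted over the list alone; adjusted p = 0.99) and 1 and 4 with Ab2 (1 and 3 adjusted over the list alone; adjusted p = 0.54). Sorcs3 had 0.25 and 0.26, Rheb had −0.31 with Ab1 and Inhba −0.68 with Ab2, and the calls of Rheb and Inhba ended without replicate 2 of WT Ab1 and of WT Ab2, that of Rheb also without replicate 1 of WT input and with DESeq2, which gave no adjusted p to Inhba.

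Genes over 100 kb exceeded the others over input by 0.11 with Ab1 (1057 above, 381 below, p = 2.1e-13, and p = 0.00034 with an estimated correlation) and by 0.10 with Ab2 (1036 above, 435 below, p = 3.6e-10, and p = 0.00092 with an estimated correlation). The class of highest mCA exceeded the lowest by 0.52 and 0.51. For Ab1 against input in WT and Ab2 against input in WT, DESeq2 called 2385 of 11672 and 2535 of 11324 genes with an adjusted p. Without replicate 2 of WT Ab1 the Ab1 count was 2723 (1613 above, 1110 below) and without replicate 1 of WT input it was 2882 (1667 above, 1215 below). Without replicate 2 of WT Ab2 the Ab2 count was 2981 (1763 above, 1218 below) and without that input it was 3039 (1738 above, 1301 below). The share of calls above input was 54.8% for Ab1 with TMM, 35.5% with library totals and 15.8% with unscaled counts, and 55.6%, 38.7% and 15.8% for Ab2.

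Precipitates from KO chromatin, or with pre-immune serum, also differed from input. In KO, Ab1 differed at 5505 genes (3000 above, 2505 below) and Ab2 at 5051 (2815 above, 2236 below), and pre-immune serum differed at 5363 in WT (2935 above, 2428 below) and at 5571 in KO (3048 above, 2523 below). Malrd1 was above input by 0.51 with Ab1 in KO (adjusted p = 6.3e-24), by 0.52 with Ab2 in KO and by 0.49 with pre-immune serum in WT. Skint5 (0.83) and Skint6 (0.80), of a gene family named for the selection of skin T cells, led with pre-immune serum in WT. Spag16 (0.46) and the glypican Gpc5 (0.39) were above input there as well. Skint6 had 0.79 with Ab2 in KO but, outside the rule, 0.26 with Ab1 in WT. Spag16 (0.49), Gpc5 (0.43) and the fibrocystin gene Pkhd1 (0.56) were above input with Ab1 in KO, and Msra was below it (−0.64). Ab2 in KO gave Pkhd1 (0.55), Gpc5 (0.39) and 1700007B14Rik (0.50), and pre-immune serum in KO gave Malrd1 (0.50), Spag16 (0.47), Skint6 (0.80), 1700007B14Rik (0.53) and Pkhd1 (0.55). Mecp2 had −0.21 with pre-immune serum in WT (adjusted p = 0.10), −0.12 with Ab1 in KO (adjusted p = 0.42), −0.17 with Ab2 in KO (adjusted p = 0.23) and −0.18 with pre-immune serum in KO (adjusted p = 0.20).

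With the preset correlation, several lists differed from input in these controls in the same direction as with antibody in WT. No list passed in them with an estimated correlation (lowest adjusted p = 0.08). MeCP2 partners had 0 of 23 members above and 6 below with pre-immune serum in WT (the same adjusted over the list alone; adjusted p = 0.0055), and 0 and 7 with either antibody in KO (also adjusted over the list alone; adjusted p = 0.0072 for each). Genes of liver, muscle, blood and skin had 13 of 38 above and 1 below with pre-immune serum, 9 and 1 with Ab1 in KO and 8 and 1 with Ab2 in KO, each count the same adjusted over the list alone (adjusted p = 0.0055, 0.022 and 0.014). Microglia and vascular markers had 9 of 26 above and 1 below with pre-immune serum (10 and 1 adjusted over the list alone), 11 and 2 with Ab1 in KO and 12 and 0 with Ab2 in KO, both the same adjusted over the list alone (adjusted p = 0.019, 0.014 and 0.0092). Inhibitory neuron markers had 6 of 21 above and 3 below, 7 and 2, and 8 and 2, again the same adjusted over the list alone (adjusted p = 0.023, 0.014 and 0.014), and with pre-immune serum their median relative to all genes turned to −0.041 without replicate 2 of WT pre-immune serum and to −0.031 without replicate 1 of WT input.

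Excitatory neuron markers passed as a list below input in Ab1 and Ab2 in KO and pre-immune serum in WT with the preset correlation, but not with an estimated correlation (lowest adjusted p = 0.08). They had 5 of 25 above and 9 below with pre-immune serum (5 and 10 adjusted over the list alone; median −0.15, adjusted p = 0.0067), 5 and 11 with Ab1 in KO (5 and 13 adjusted over the list alone; median −0.26, adjusted p = 0.0044) and 3 and 9 with Ab2 in KO (4 and 9 adjusted over the list alone; median −0.24, adjusted p = 0.0072). The targets named in earlier work were below input as well, with adjusted p = 0.031, 0.014 and 0.022. These calls also ended with an estimated correlation.

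Genes over 100 kb did not pass camera with the preset correlation in these controls, with differences of 0.013 for pre-immune serum in WT (p = 0.14), 0.0035 for Ab1 in KO (p = 0.26) and 0.0042 for Ab2 in KO (p = 0.27). With a boundary of 200 kb the differences were 0.041, 0.034 and 0.036, which passed with the preset correlation but not with an estimated correlation (p = 0.06, 0.11 and 0.11). The class of highest mCA exceeded the lowest by 0.16, 0.13 and 0.13. Within 5 classes of the ratio of CG to CA calls, a stand-in for base composition, that difference ran from −0.099 to 0.26, from −0.099 to 0.24 and from −0.15 to 0.25, so its sign depended on the class. With Ab1 in KO the medians ran from −0.079 in the lowest class down to −0.13 in the third, up to 0.10 in the eighth and back to 0.047 in the highest. Across 16467 genes, which are not independent replicates, the log2 fold change over input in these controls had rank correlations of 0.38, 0.37 and 0.37 with the CG methylation level, 0.26, 0.23 and 0.23 with mCA, and 0.094, 0.084 and 0.090 with span. Over input in WT, Ab1 and Ab2 had 0.20 and 0.22 with CG methylation and 0.60 and 0.59 with mCA. Of the Ab1 calls in KO, 98.1% had the same sign with pre-immune serum in WT, with which they share no library, and 2242 genes were above input in both, against 494 for independent lists. Outside the rule, and chosen from genes named in other comparisons, Sox6 had 0.29 with Ab1 in KO and 0.30 with pre-immune serum. Ncor2 had −0.62 and −0.67, and Mapk8ip1 −0.81 and −1.03. Auts2, chosen in the same way, had −0.13 and −0.097 against 0.21 with Ab1 in WT. DESeq2 called 3055 genes for Ab1 in KO, 2781 for Ab2 in KO, 2886 for pre-immune against input in WT, and 3021 for pre-immune against input in KO, of 14800, 14800, 14453 and 13757 with an adjusted p. The shares of calls above input were 54.5%, 55.7% and 54.7% with TMM and 15.2%, 14.4% and 14.8% with unscaled counts. Without replicate 1 of WT input pre-immune serum had 3471 calls (1485 below) and without replicate 2 of WT pre-immune serum 3476 (1491 below). Ab1 in KO had 1558 calls below input without replicate 2 of KO Ab1 and 1641 without replicate 1 of KO input. Ab2 in KO had 3226 calls (1863 above, 1363 below) without that input and 1458 below without replicate 2 of KO Ab2. For pre-immune against input in KO the count was 3645 (2024 above, 1621 below) without replicate 1 of KO input and 3651 (1557 below) without replicate 2 of KO pre-immune serum.

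**Figure D2:**
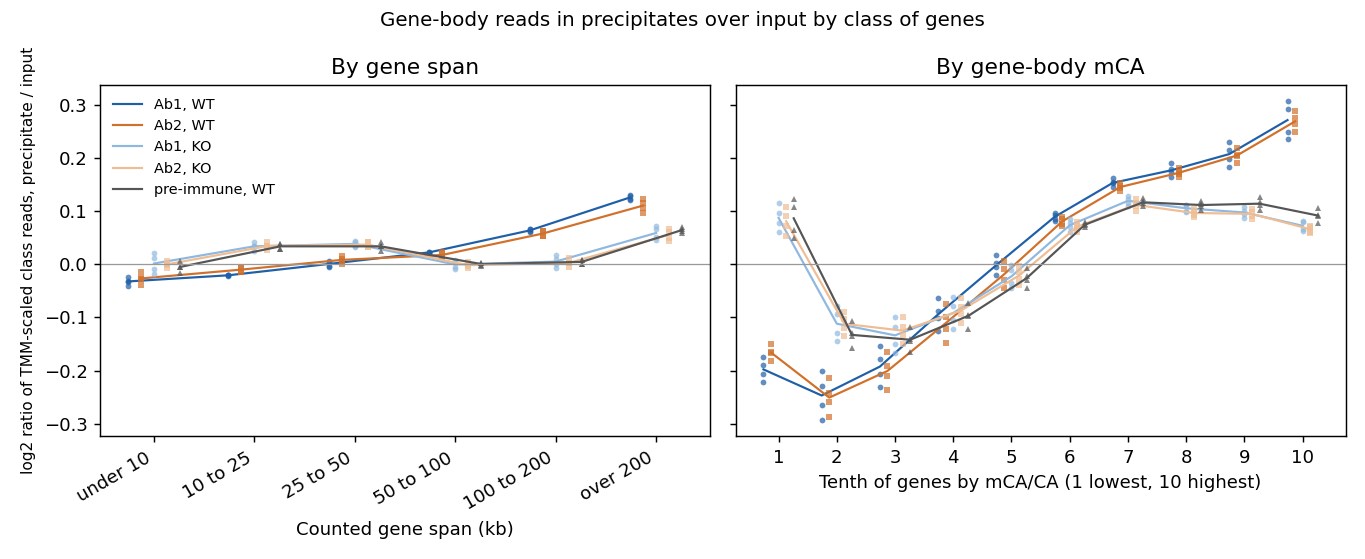
Log2 ratio of TMM-scaled reads in precipitates over input of the same genotype, summed over genes of each counted span in kb (left) and of each mCA class from 1, lowest, to 10, highest (right). Points are the 4 ratios between 2 precipitate and 2 input libraries, lines their means; the 3 controls (Ab1 and Ab2 in KO, pre-immune serum in WT) overlie each other, and the WT antibody libraries lie below them in mCA classes 1 and 2 and above them in classes 8 to 10 and in spans over 200 kb.

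Set against pre-immune serum directly, in comparisons added after the data were seen, KO antibody libraries gave 0 genes by edgeR's test with Ab1 (663 at an unadjusted p under 0.05, and DESeq2 called 0 with 102 unadjusted) and 0 with Ab2 (768 unadjusted, and DESeq2 called 0 with 100 unadjusted). The genes with the smallest p were Gldc of glycine cleavage (−0.37, adjusted p = 0.12) and Kbtbd2 (0.56) for Ab1, followed by Usp35 (0.72), Pou4f1 (1.40) and Tmem209 (−0.36). For Ab2 they were Tpk1 (−0.16), Emp2 (0.52), Lilr4b (−1.32), Fbxw27 (−0.55) and Gnptg (1.69), and Mecp2 had 0.059 with Ab1 and 0.0085 with Ab2. In WT, Ab1 differed from pre-immune serum at 2247 genes (1219 higher, 1028 lower) and Ab2 at 1789 (1022 higher, 767 lower). Auts2 had 0.31 in each, Msi2 had 0.42 with Ab1, and Pbx3 (0.46), Camta1 (0.34) and Dhrsx (1.16) led with Ab2, while Skint5 (−0.57), Csprs (−0.82) and Gm14403 (−0.43) were lower with Ab1 and Skint6 (−0.49) with Ab2. Mecp2 had −0.19 (adjusted p = 0.28) and −0.25 (adjusted p = 0.14). Excitatory neuron markers had 10 of 25 higher and 0 lower with Ab1 (10 and 0 adjusted over the list alone; adjusted p = 6.9e-09, and adjusted p = 0.0045 with an estimated correlation) and 7 and 0 with Ab2 (8 and 0 adjusted over the list alone; adjusted p = 9.9e-06, and adjusted p = 0.018 with an estimated correlation). DESeq2 called 840 of 10977 and 625 of 6458 genes with an adjusted p, which Dhrsx lacked with Ab2. Without replicate 2 of WT pre-immune serum the edgeR counts were 1040 (624 higher, 416 lower) and 701 (451 higher, 250 lower). For Ab1 against pre-immune in WT, the count was 1165 (628 higher, 537 lower) without replicate 2 of WT Ab1, and 629 were lower without its replicate 1. For Ab2 against pre-immune in WT the count was 848 (549 higher, 299 lower) without replicate 1 of WT Ab2, 1084 (583 higher, 501 lower) without its replicate 2 and 1178 (633 higher) without replicate 1 of WT pre-immune serum. The share higher was 54.3% and 57.1% with TMM, 39.7% and 43.2% with library totals, and 76.3% and 78.5% with unscaled counts.

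After correction for input, the antibody signal still differed between WT and KO. Tenm3 had 0.45 with Ab1 (SE 0.05, adjusted p = 1.8e-09), and Auts2 0.34 with either antibody (adjusted p = 1.6e-08 and 2.8e-08). The transcription factor Camta1 had 0.38 and 0.37, the ephrin Efna5 0.44 and 0.48, Tcf4 0.45 with Ab1, and Msi2 (0.44) and Dhrsx (1.34) were among the first with Ab2. Mecp2 had −0.29 (adjusted p = 0.27) and −0.30 (adjusted p = 0.30). With Ab1 1076 genes differed (683 higher, 393 lower) and with Ab2 618 (445 higher, 173 lower), and both share the same inputs. For Ab1 over input WT against KO and Ab2 over input WT against KO, the replicate number as a block gave 1616 and 1101 calls.

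Excitatory neuron markers had 8 of 25 higher and 0 lower with Ab1 (9 and 0 adjusted over the list alone; adjusted p = 4.8e-08, and adjusted p = 0.0057 with an estimated correlation) and 5 and 0 with Ab2 (7 and 0 adjusted over the list alone; adjusted p = 0.00014, and adjusted p = 0.035 with an estimated correlation). Long neuronal genes had 12 of 45 higher with Ab1 (15 adjusted over the list alone; adjusted p = 1.5e-07) and 7 with Ab2 (9 adjusted over the list alone; adjusted p = 0.00035), with adjusted p = 0.19 and 0.45 with an estimated correlation. Ubiquitously expressed genes had 1 of 40 lower with Ab1 and 0 with Ab2 by edgeR's test (0 and 0 adjusted over the list alone), with medians of −0.20 (adjusted p = 0.00046) and −0.13 (adjusted p = 0.01), and with adjusted p = 0.12 and 0.25 with an estimated correlation. Astrocyte markers (adjusted p = 0.033 and 0.0071) and the targets named in earlier work (adjusted p = 0.00053 and 0.0028) passed as well, though not with an estimated correlation (adjusted p = 0.12 and 0.067, and 0.12 and 0.16). Genes over 100 kb exceeded others by 0.096 with Ab1 (p = 2.7e-11, and p = 0.00062 with an estimated correlation) and 0.079 with Ab2 (p = 8.0e-10, and p = 0.0011 with an estimated correlation), and the highest mCA class exceeded the lowest by 0.44 and 0.41. DESeq2 called 423 of 4720 and 270 of 5068 genes with an adjusted p, which Dhrsx lacked with Ab2. Without replicate 1 of KO input the edgeR counts were 527 (400 higher, 127 lower) and 306 (249 higher, 57 lower), and without replicate 2 of WT input 569 (407 higher, 162 lower) and 347 (265 higher, 82 lower). With Ab1 they were 614 (414 higher, 200 lower) without replicate 2 of KO Ab1 and 635 (407 higher, 228 lower) without replicate 2 of WT Ab1. With Ab2 they were 345 (271 higher, 74 lower) without replicate 2 of KO Ab2, and 112 were lower without replicate 1 of WT Ab2. The share higher was 63.5% and 72.0% with TMM, 46.9% and 56.7% with library totals, and 84.5% and 87.6% with unscaled counts.

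**Figure D3:**
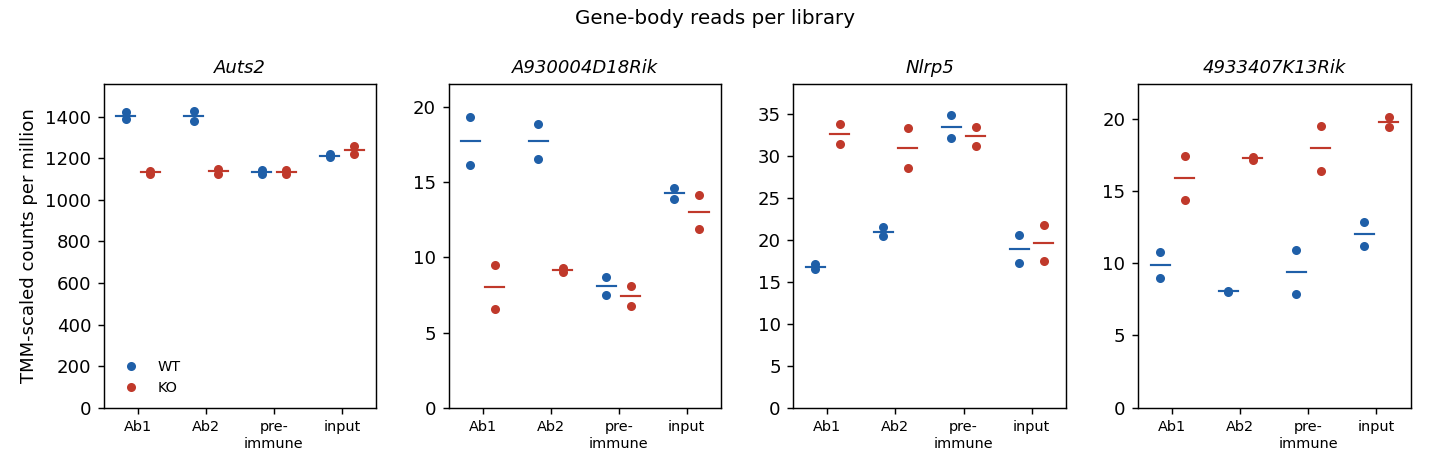
TMM-scaled CPM of 4 genes in each library, WT in blue and KO in red, with bars at the means of 2 libraries; these genes were chosen for the plot after their values were seen, in place of Vps37b and Cldn12. Antibody libraries of WT lie above those of KO at Auts2 and A930004D18Rik and below them at Nlrp5, where pre-immune serum and input do not part, while 4933407K13Rik is lower in WT in all 4 kinds of library.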

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

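The difference in genotype effect between the antibodies, a planned comparison, stood out in 2 gene lists. Long neuronal adhesion and synapse genes had a median of 0.025 for the Ab1 effect minus the Ab2 effect (45 members, adjusted p = 0.03 with the preset correlation and adjusted p = 0.80 with an estimated correlation). Excitatory neuron markers had 0.053 (25 members, adjusted p = 0.03 with the preset correlation and adjusted p = 0.21 with an estimated correlation). No member of either list passed edgeR's test for this difference, in which 728 genes had an unadjusted p under 0.05, and DESeq2 called 0 genes. Without replicate 1 of WT Ab1, replicate 1 of KO Ab2 or replicate 2 of KO Ab1 the long neuronal list no longer passed, and without replicate 2 of WT Ab2 its value turned to −0.0021. The excitatory list no longer passed without replicate 1 of KO Ab2, replicate 2 of WT Ab1, replicate 2 of WT Ab2 or replicate 2 of KO Ab1. These values are given without an explanation.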

How the results depend on the processing

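Alternatives and tests of comparisons were fixed before the data were examined, except unscaled counts, the fit without chromosome Y and unplaced contigs, the analyses by methylation with their call minimums, and the comparisons with pre-immune serum named as added, which were chosen after seeing the data. The tests of explanations for the mCA trend, the KO background and 4933407K13Rik were set later, and all but those on base composition and on the neighbours of 4933407K13Rik after their results were seen. The value followed for a gene list was first its median, and was changed to that median minus the median of all genes after the first table showed many reversals with unscaled counts. Sign changes between 2 values that both miss the threshold were not counted as reversals where they were within 1 SE or had no SE. Of the alternative values for named genes, 5074 kept direction and side of the threshold, 116 no longer passed, 25 newly passed and 1 reversed; for lists these numbers were 3381, 113, 8 and 7; for the long-gene and mCA differences 600, 2, 14 and 1. Of the counts, 1223 stayed within 1.5 times and 191 did not. The long-gene differences of both antibodies between WT and KO passed under every alternative run. So did the class of highest mCA against all other genes. Genes under 10 kb had a median of 25.8 reads and genes over 200 kb 2103, so counting error is largest in short genes. Simulated 1.2-fold changes were recovered in 26.9% of changed genes. These were few, and drawn without regard to length from genes with a mean count of at least 20. GC corrections, alone or with the replicate block, were not run. Where no reason is given, the cause was not tested.

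The long-gene and mCA calls here are with the preset correlation. With unscaled counts the long-gene difference over input in WT was 0.11 for Ab1 and 0.10 for Ab2 and no longer passed. It newly passed at 0.012 for pre-immune serum in WT, 0.0027 for Ab1 in KO, 0.0036 for Ab2 in KO and 0.014 for the difference between antibodies, and turned to −0.00040 for the long-gene difference, pre-immune against input in KO. With unscaled counts the median of all genes over input was −0.13 to −0.22. Inhibitory neuron markers reversed over input without a filter, to −0.017 for Ab2 in WT and −0.027 for pre-immune serum in WT, and with DESeq2, to −0.017 and −0.027. With a mean count of at least 50 the mCA difference in input of WT against KO was −0.025. There the class of highest mCA newly passed against all other genes. With the compared groups alone 1 gene was called in input and the long-gene difference of pre-immune serum over input in WT passed at 0.013. With a boundary of 200 kb this difference newly passed at 0.041, with 0.034 for Ab1 and 0.036 for Ab2 over input in KO, 0.015 between antibodies and 0.031 for pre-immune serum over input in KO, and none of these passed with an estimated correlation (p = 0.06, 0.11, 0.11, 0.22 and 0.14).

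DESeq2 called fewer genes than edgeR: 949 for Ab1 and 650 for Ab2 in WT against KO, 0 for pre-immune serum, 2385 and 2535 for Ab1 and Ab2 over input in WT, 2886 for pre-immune serum, 3055 and 2781 for Ab1 and Ab2 over input in KO, 423 and 270 for the effects corrected for input, 840 and 625 against pre-immune serum in WT, and 3021 for pre-immune serum over input in KO. Its own filter left an adjusted p to 4720 to 14800 of 17929 genes in these comparisons. For pre-immune serum between WT and KO it left an adjusted p to all genes. A gene without an adjusted p was counted as not passing. The filter was not the only difference, as DESeq2 had fewer genes at an unadjusted p under 0.05 as well. For Ab1 in WT against KO these were 2540, against 4616 with edgeR. With pre-immune serum they were 89 against 744, and in input 67 against 694. DESeq2's test was thus the stricter before adjustment, and a gene it did not call may reflect this.

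The labels do not say that a replicate number marks a shared animal or day, and deviations correlated at only −0.0002 to 0.054 over 28 pairs of groups, so the replicate block was not used for the values reported. The numbers do share a small effect, since 27 of these correlations were positive. Scaled reads in replicate 2 were higher than in replicate 1 in 8 of 8 groups in the mCA classes 9 and 10 and in spans under 10 kb, and lower in 8 of 8 groups in classes 2 to 5 and in spans of 50 to 100 kb (log2 ratio 0.0022 to 0.058 in class 10 and −0.065 to −0.015 in class 2). Each group holds both numbers, and with the block the mCA difference, Ab1 WT against KO was 0.41 and the mCA difference, Ab2 WT against KO was 0.38. What the numbers share was not tested. For Ab1 over input WT against KO and Ab2 over input WT against KO, the replicate block gave 1616 and 1101 calls, and the block within genotype 1634 and 1104. With the replicate block 2 genes were called with pre-immune serum, 1 in input, and 1 for each antibody against pre-immune serum in KO, which was 1 and 1 also with the block within genotype. It moved no other such total over 1.5 times. Oligodendrocyte markers no longer passed between WT and KO with either antibody (0.087 and 0.082 relative to all genes), Abcb1a, Dsg3, Cps1 and Tet1 newly passed with Ab2, as did Prkd2 with pre-immune serum, 4933407K13Rik in input, and Gldc and Tpk1 against pre-immune serum in KO, and no other call of a named gene or list changed.

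Leaving out 1 library at a time leaves a group with a single library, which is taken to vary like the others. Counts of calls then ran from 1265 to 2406 for Ab1 and 731 to 1742 for Ab2 in WT against KO, 0 to 2 for pre-immune serum, 2723 to 4879 for Ab1 and 2981 to 5118 for Ab2 over input in WT, 3471 to 5381 for pre-immune serum over input in WT, 3226 to 5075 for Ab2 over input in KO, 3645 to 5579 for pre-immune serum over input in KO, 527 to 1114 and 306 to 635 for the Ab1 and Ab2 effects corrected for input, and 1040 to 2276 and 701 to 1809 for Ab1 and Ab2 against pre-immune serum in WT. Without replicate 2 of WT pre-immune serum or replicate 1 of WT input, inhibitory neuron markers reversed for pre-immune serum over input in WT (range −0.041 to 0.22). For the difference between antibodies, long neuronal genes reversed without replicate 2 of WT Ab2 (range −0.0021 to 0.050) and the long-gene difference ranged from −0.00066 to 0.026. Mecp2 for Ab1 against pre-immune in KO reversed without replicate 1 of KO Ab1 (range −0.050 to 0.16).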

Other observations

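The tests on mCA, on the KO background and on 4933407K13Rik were chosen after the results were seen, except those on base composition and on the neighbours of 4933407K13Rik, which were set before their results were seen; the values within classes of the ratio of CG to CA calls were added later.

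Skint5, Skint6 and Nlrp5, chosen after their values were seen, have mCA levels of 0.701%, 0.665% and 0.687%. Over input, Skint5 and Skint6, of a family named for the selection of skin T cells, had log2 fold changes of 0.83 and 0.80 with pre-immune serum in WT but 0.26 each with Ab1 in WT. Nlrp5, expressed in oocytes, had 33.5 ± 1.91 CPM with pre-immune serum in WT and 32.3 ± 1.67 CPM in KO, 18.9 ± 2.38 CPM in WT input, and 16.8 ± 0.466 CPM with Ab1 in WT (SD, n = 2 each). Excitatory neuron markers were below input in Ab1 and Ab2 in KO and pre-immune serum in WT with the preset correlation, but not with an estimated correlation (lowest adjusted p = 0.08). In WT the list had adjusted p = 0.25 with Ab1 and 0.91 with Ab2. The genotype effect corrected for input was positive for them, with adjusted p = 4.8e-08 and 0.00014, and with adjusted p = 0.0057 and 0.035 with an estimated correlation.

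Antibody signal in WT over KO increased with gene-body mCA. A genotype difference that needs no antibody is argued against by the pre-immune libraries, where the highest mCA class minus the lowest was −0.021. A precipitation background, taken as pre-immune serum over input in KO, had rank correlations across genes of −0.31 with the Ab1 difference and 0.24 with mCA. Signs such as these would make the difference fall with mCA, whereas it rose. Holding that profile could therefore only raise the partial rank correlation with mCA, which was 0.53. That value is no test of the background. Low counts as the whole cause are argued against by a class difference of 0.27 among 2842 genes with a mean count of at least 500. The mCA classes were formed anew from these genes. The value can therefore not be set in size against the class difference of 0.41 over all classed genes. For base composition, the ratio of CG to CA calls served as a stand-in. That ratio had a rank correlation of 0.35 with the Ab1 difference but only 0.040 with mCA. By rank, the ratio could therefore hardly carry the mCA trend. Holding it could also hardly move the correlation with mCA, which was 0.39 with ratio and span held. Given mCA and span, the ratio itself had a partial rank correlation of 0.39 with the Ab1 difference, as large as that of mCA. With Ab1 over input the same partial correlation was −0.25 in WT and −0.45 in KO, so its sign depended on the comparison. Within 5 classes of the ratio the mCA difference was 0.35 to 0.46 with Ab1 and 0.32 to 0.43 with Ab2. GC content itself was not measured, so an effect of it that the ratio does not carry stays open. MeCP2 occupancy that follows mCA may account for the trend, as a hypothesis. The smaller correlation of the antibodies with mCA, 0.41, restates the trend and does not test this hypothesis. That of pre-immune serum was −0.037.

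In KO, antibody precipitates differed from input at 5505 genes with Ab1 and 5051 with Ab2. Binding of both antibodies to a shared target other than MeCP2 is argued against as the source of most of these differences. At genes called for Ab2 over input in KO, Ab1 minus pre-immune serum in KO, signed by the Ab2 direction, had a median of 0.00096. Binding particular to 1 antibody would not show in that median. Against pre-immune serum in KO, 0 genes passed edgeR's test with Ab1 and 0 with Ab2. A precipitation background that needs neither MeCP2 nor a specific antibody may be its source, since 98.1% of the Ab1 calls in KO had the same sign with pre-immune serum in WT. Across genes the background followed CG methylation (rank correlations of 0.37 to 0.38 in Ab1 and Ab2 in KO and pre-immune serum in WT) more closely than mCA (0.23 to 0.26), and had rank correlations of −0.41 to −0.39 with the ratio of CG to CA calls, which does not settle what sets it, and no biological explanation was tested.

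4933407K13Rik, chosen after its values were seen, had more reads in KO than in WT. MeCP2 or antibody binding there is argued against by input, which was not precipitated and had −0.71 (SE 0.15, adjusted p = 0.093, unadjusted p = 5.2e-06). A copy-number difference over about 1 Mb on each side is argued against by its 14 listed neighbours, whose median input difference was −0.037 (range −0.37 to 0.43). A difference of this locus carried with the KO allele, 1.64 Mb from Mecp2, or reads from near-identical copies elsewhere could explain it, as both KO libraries lay above both WT libraries in 4 of 4 kinds of library. These explanations cannot be told apart because KO tissue was compared with WT tissue alone and no reads were analysed here.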
